A study of Mus musculus with 9 samples.

How the data were processed

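Kidney RNA was measured in 9 samples, 3 per group, by sequencing of poly(A)-selected, strand-marked, paired-end libraries, per the labels' protocols. Per the submitters' processing notes, CASAVA, cutadapt and HISAT2 were used with the mm10 mouse genome; versions and the read counter are not given in the sources used here. The authors deposited a table of 54532 genes with 1 column per sample. The deposited values behave as FPKM (reads divided by gene length and by a constant of the library), as each value times the deposited gene length and a constant of the library gave a whole number of reads, for 100% of values within a tolerance of 0.01. That constant followed size factors from medians of ratios more closely than total reads, so the FPKM of a library do not refer to its total.

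The coordinates of 98.3% of genes are those of GENCODE mouse release 21. Named genes are given by symbol as in the deposited table; where a symbol belonged to several tested genes its identifier was added. Reads recovered from the values gave the depth of each library (7595631 to 15141784); 3 reads, taken as the floor, are 2.33e-05% to 0.000191% of the reads outside the mitochondrial genome, which covers counting error only. No pair of libraries agreed within sampling noise, so all 9 were kept.

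A count model had been planned before the data were examined, with limma on log2(value + 1) if no counts were found. As the values were FPKM, the latter was used: limma 3.58.1 in R 4.3.3, empirical Bayes with a trend, all 9 samples in 1 fit of 3 groups without a block, and Benjamini-Hochberg adjusted p under 0.05. Genes with FPKM of at least 1 in at least 3 libraries were tested (12642 genes). Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes; in simulated data a true log2 of 2 was fitted at a median of 1.49 (unloaded against ground control). Gene lists (34, of which 28 had at least 4 tested members) were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry, also from limma, on the same log2(FPKM + 1) values. Figures used Python 3.11.15 and matplotlib 3.10.9.

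Simulated data with the spread of these libraries and 200 changed genes were used to test the code. Of genes changed by a log2 of 2, 18.6% were found in unloaded against ground control and 31.2% in 4-PBA against unloaded, and 0% of genes changed by 1 in either.

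The genes named follow a rule fixed in advance: among protein-coding genes past the threshold with an assigned symbol, a mean of at least 1 CPM in the higher group and groups that do not overlap, the 10 largest rises and falls; the 10 smallest p where fewer than 5 genes passed; the 10 largest changed back; up to 4 members per list; and 7 endoplasmic reticulum stress genes. Of the genes so chosen, 2 are not reported here. To keep the text short, list members are named only for lists that passed in that comparison and for both stress lists, a limit set after the results were seen, as was the division of the unloaded libraries between both comparisons.

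Alternatives covered scaling, filters, the samples in the fit, a replicate block, limma-voom on recovered reads, a fold threshold, protein-coding genes, pseudocounts of 0.1 and 4, the mitochondrial share as a covariate, library weights, thinned reads, each sample left out in turn, and both PBA3 and GC3 left out.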

Results

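Kidney messenger RNA was sequenced from male C57BL/6J mice aged 4 months in 3 groups of 3 samples. Ground controls were left untreated, hindlimb-unloaded mice received vehicle, and treated hindlimb-unloaded mice received 4-phenylbutyric acid (4-PBA, a chemical chaperone that lowers endoplasmic reticulum stress) by intraperitoneal injection at 100 mg per kg per day. Hindlimb unloading lifts the hind limbs off the ground and is used as a model of disuse and of microgravity. Libraries are called GC1 to GC3, HU1 to HU3 and PBA1 to PBA3 below. Reads assigned to genes ranged from 7595631 (HU2) to 15141784 (GC2) per library. The limma p-values given measure the spread between these samples, estimated over all 3 groups. The camera p-values at a preset correlation rest mainly on the spread between genes and do not measure that between samples.

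The libraries differed in the share of reads from the mitochondrial genome. It was 18.9% in GC1, 14.8% in GC2 and 49.7% in GC3, and 68.7%, 79.3% and 63.7% in HU1, HU2 and HU3. PBA1 and PBA2 had 15.2% and 13.7%, while PBA3 had 67.1%. Reads outside the mitochondrial genome therefore numbered 2550139, 1568888 and 3037972 in HU1, HU2 and HU3, and 10592475, 12893802 and 5780141 in GC1, GC2 and GC3. PBA1, PBA2 and PBA3 had 12390406, 12824889 and 2887586. Pseudogenes took 5.84%, 7.54% and 3.73% of those reads in HU1, HU2 and HU3, 4.83% in PBA3, and 0.955% to 1.76% in the other 5 libraries.

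**Figure D1:**
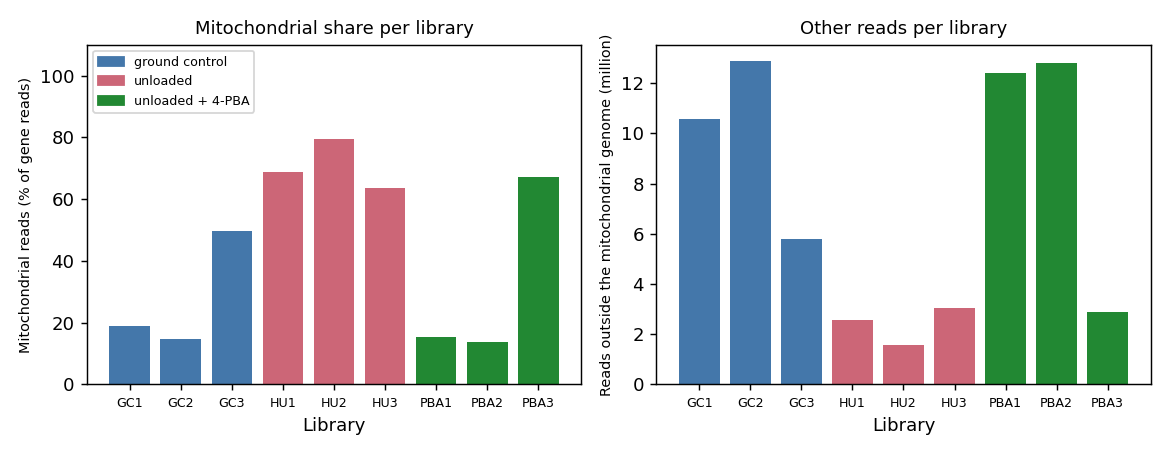
Share of gene-assigned reads from the mitochondrial genome in percent (left) and number of other reads, from 1568888 in HU2 to 12893802 in GC2 (right), with 1 bar per library coloured by group. GC3 (49.7%) and PBA3 (67.1%) lie above the rest of their groups, and the unloaded libraries lie between 63.7% and 79.3%.

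The first comparison, unloaded mice against ground controls, asked how kidney gene expression differed after unloading. As ground controls were untreated and unloaded mice received vehicle, it does not separate unloading from vehicle, and unloading stands for both below. Among the genes that fell was Slc22a2 (ENSMUSG00000040966; mm10 chromosome 17, 12584132 to 12628488), which encodes an organic cation transporter of the proximal tubule, the nephron segment that reabsorbs most of the filtrate. It had 112 ± 6.6 FPKM in ground controls and 4.96 ± 2.51 FPKM in unloaded mice (SD, n = 3 each), a log2 difference of -4.34 ± 0.64 (SE; limma adjusted p = 0.00870). Kap (ENSMUSG00000032758; chromosome 6, 133849851 to 133853762), an androgen-regulated proximal tubule transcript, had 52225 ± 5688 FPKM against 2678 ± 381 FPKM (SD, n = 3 each; log2 difference -4.29, limma adjusted p = 0.0139). Among the genes that rose, Nid1 (ENSMUSG00000005397; chromosome 13, 13437551 to 13512269), which encodes the basement membrane protein nidogen-1, went from 5.96 ± 3.14 to 93.9 ± 44.2 FPKM (SD, n = 3 each), a log2 difference of 3.72 ± 0.89 (SE; limma adjusted p = 0.0319).

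In all, 1292 of 12642 genes tested passed the threshold in limma, 672 higher and 620 lower. Of these, 455 higher and 570 lower genes were protein-coding, and 217 higher and 50 lower genes were of other classes. The 2 groups did not overlap in 37.7% of the genes tested, where chance gives 10%. The balance of higher and lower genes depended on the scaling. With scaling by total reads the median of all genes moved to -0.79 and the counts were 270 higher and 1986 lower, and with scaling by reads outside the mitochondrial genome the median was 0.21 and the counts were 1082 and 479. With limma-voom on recovered reads they were 845 and 479.

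By the rule for named genes, the largest falls among protein-coding genes were in Slc22a28, Slc22a2, Mogat1, Tmem37, Kap, Cyp2d9, Slc22a18, Cyp4b1, Nat8f1 and Cyp4a31, with log2 differences from -4.51 to -3.85. Several of these have close paralogs (Slc22a28, Cyp2d9, Nat8f1, Cyp4a31), so reads could be split between copies. Among the largest rises were C7, Nid1, Duxf3, Fbln5, Serping1, Ctsk, Clca3a1, Ecm1 and Spon1, from 4.36 to 3.54. C7 encodes a terminal complement component, Serping1 the C1 inhibitor, Fbln5 the elastic fibre protein fibulin-5 and Ctsk the collagen-degrading protease cathepsin K. Duxf3 belongs to a repeated gene family and its value is uncertain. In the treated library PBA3, C7 had 33.7 FPKM and Nid1 57.3 FPKM, against 0.883 and 5.77 FPKM in PBA1.

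**Figure D2:**
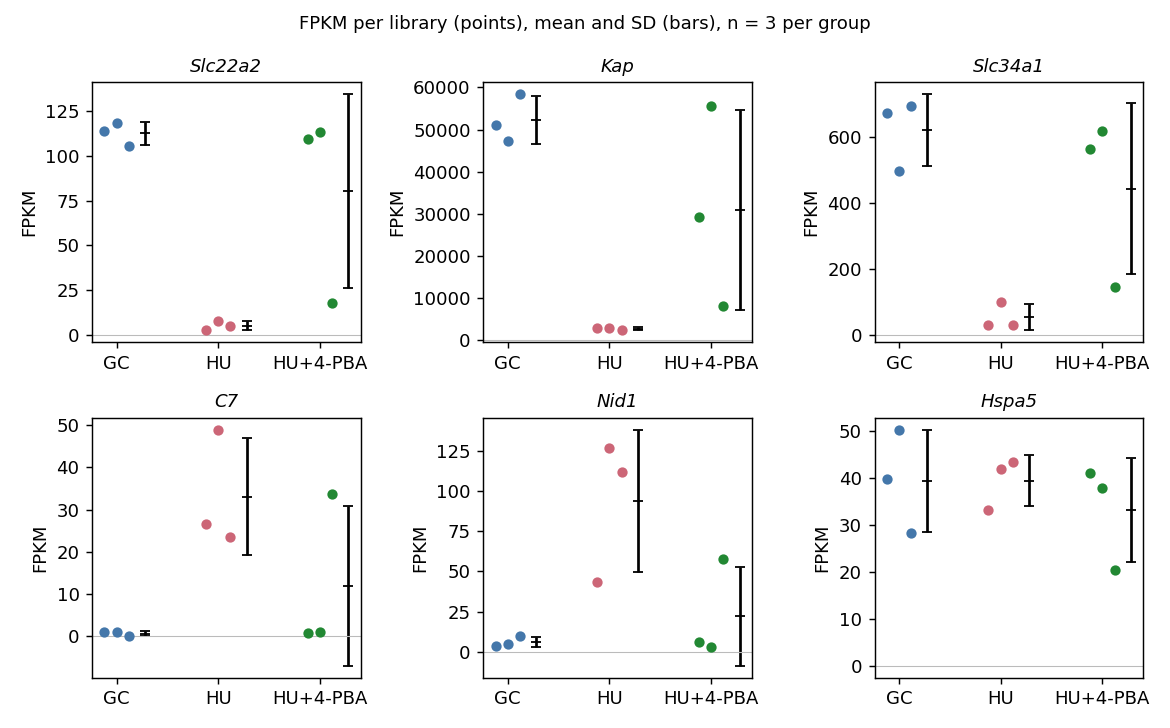
FPKM of 6 genes in each library (points) with the group mean and SD (bars, n = 3); GC, ground control, HU, unloaded. Slc22a2, Kap and Slc34a1 were low and C7 and Nid1 high in the unloaded libraries, PBA3 lay nearer to them than PBA1 and PBA2 did, and Hspa5 averaged 39.5 FPKM in both GC and HU.

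Among the gene lists fixed in advance, 12 of 21 proximal tubule genes fell and none rose, and 17 fell when adjusted over the list alone. The examples were Slc22a30 (27.6 ± 2.65 to 2.53 ± 0.884 FPKM) and Slc7a13, a cystine and aspartate transporter of the late segment (299.6 ± 74.2 to 37.1 ± 17.4 FPKM; SD, n = 3 each). Of 10 intercalated cell genes 4 fell, and 5 when adjusted over the list alone, among them the anion exchanger Slc26a4 (log2 difference -2.62) and the ammonia channel Rhcg (-3.11). Of 34 oxidative phosphorylation genes encoded in the nucleus 6 fell, and 10 when adjusted over the list alone, including Ndufa1 (-1.83) and Ndufb9 (-1.71). Of 20 antioxidant genes 5 fell, and 7 when adjusted over the list alone, including Gstp1 (-1.28) and Sod1 (-1.87). Of 24 extracellular matrix genes 5 rose, and 18 when adjusted over the list alone. Examples were Bgn, encoding biglycan (26.8 ± 5.05 to 242 ± 93.1 FPKM; SD, n = 3 each), and the metalloproteinase inhibitor Timp1 (log2 difference 2.33). Of 15 immediate early genes only Klf6 rose (1.40), and 2 rose when adjusted over the list alone (list median 0.57 above that of all genes, and 0.57 above it with scaling by total reads).

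These 6 lists of 28 tested passed camera with a preset correlation between genes, 2 upwards and 4 downwards. The camera adjusted p was 1.55e-10 for the proximal tubule, 3.59e-07 for the matrix, 1.47e-05 for oxidative phosphorylation, 0.000362 for intercalated cells, 0.00551 for antioxidant genes and 0.0379 for immediate early genes. With an estimated correlation 0 lists passed, and with fry only the intercalated cell list did: the adjusted p was 0.692 with an estimated correlation for the proximal tubule, matrix, antioxidant and immediate early lists, 0.695 for oxidative phosphorylation and 0.655 for intercalated cells. With the mitochondrial share as a covariate camera called 2 lists, without a filter on low values 15, and other splits of the same 6 libraries gave up to 12.

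The study concerned endoplasmic reticulum stress, and its sensors and targets were examined by name. Hspa5, the chaperone BiP, had 39.5 ± 10.9 FPKM in ground controls and 39.5 ± 5.49 FPKM in unloaded mice (SD, n = 3 each), with a log2 difference of 0.03 ± 0.33 (SE; limma adjusted p = 0.965). Values for the other genes were -0.02 for Ddit3 (CHOP), -0.27 for Atf4, -0.71 for Xbp1, 0.28 for Atf6, 0.27 for Eif2ak3 (PERK) and 0.57 for Ern1 (IRE1), none past the threshold. In simulated data with the spread of these libraries, 0% of genes changed by a log2 of 1 were found in this comparison. Changes of that size in the stress genes would thus mostly go undetected. The values are RNA levels and do not show whether stress was present. Of 25 chaperone and degradation genes of the unfolded protein response, Syvn1 (-1.16) and Derl1 (-1.39), both part of the machinery that removes misfolded proteins, fell, and the same number fell when adjusted over the list alone (camera adjusted p = 0.129). Of 19 integrated stress response genes only Fgf21 rose, also when adjusted over the list alone (camera adjusted p = 0.732). Fgf21, a secreted metabolic hormone, had 4.42 ± 2.11 FPKM after unloading (SD, n = 3) and was listed at 0 in every ground control and 4-PBA library. At this low level, background reads piled up on few genes in the unloaded libraries, described below, are not excluded as its source.

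The count of 1292 fell most when a ground control was left out: limma called 69 genes without GC1, 230 without GC2 and 126 without GC3. It called 945 without HU1, 1033 without HU2 and 669 without HU3. Treated libraries enter only the shared estimate of spread, and the count was 874 without PBA1, 1211 without PBA2 and 2360 without PBA3. With the mitochondrial share as a covariate 109 genes passed, 76 of them among the 1292, and without any filter on low values 238 passed.

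The second comparison, 4-PBA-treated against vehicle-treated unloaded mice, asked what the drug altered during unloading. Among the genes higher with 4-PBA, Slc22a2 had 80.3 ± 54.1 FPKM with 4-PBA against 4.96 ± 2.51 FPKM without (SD, n = 3 each), a log2 difference of 3.47 ± 0.64 (SE; limma adjusted p = 0.0284). Slc12a3, the thiazide-sensitive sodium chloride cotransporter of the distal convoluted tubule, had 33.6 ± 12.3 against 3.32 ± 2.56 FPKM (SD, n = 3 each; log2 difference 3.15, limma adjusted p = 0.0146). The large SD of Slc22a2 in the treated group came from PBA3, with 17.9 FPKM.

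Of 12642 genes, 340 passed in limma, 147 higher and 193 lower with 4-PBA. Protein-coding genes made up 134 of the higher and 72 of the lower genes, and genes of other classes 13 and 121. Groups did not overlap in 20.3% of genes, where chance gives 10%. Scaling by total reads gave 572 higher and 117 lower genes with a median of 0.72, and scaling by reads outside the mitochondrial genome 125 and 322 with a median of -0.15. With limma-voom on recovered reads the counts were 128 and 321.

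The largest rises were in Tmem37, Cyp2d9, Slc22a18, Slc51a, Slc22a2, Mogat1, Nat8f1, Slc12a3, Cyp2j13 and Nat8, from 3.76 to 3.06. The largest falls were in Krtdap, Alb, Ankrd2, Colec11, Srpx, Fam69c, Fgf21, Foxa3, T2 and Guca1b. These were transcripts of low level: Alb, encoding serum albumin, had 18.9 ± 20.7 FPKM in unloaded and 0.979 ± 0.204 FPKM in treated mice (SD, n = 3 each), and was 42.6, 9.60 and 4.34 FPKM in HU1, HU2 and HU3. HU1 also stood apart in the liver list, with a mean log2(FPKM + 1) of 4.10 against 2.22 in HU2 and 1.43 in HU3. Krtdap had 9.62 ± 4.93 FPKM in unloaded mice (SD, n = 3) and was listed at 0 in each treated library. For these low transcripts too, background reads in the unloaded libraries are not excluded.

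Of 21 proximal tubule genes 4 rose, and 13 when adjusted over the list alone, with Slc22a30 (2.49) and Slc34a1, the main renal phosphate transporter (3.00), as examples. Of 10 intercalated cell genes 3 rose, and 5 when adjusted over the list alone, including Rhcg (2.59) and Slc26a4 (1.90). No gene passed among the 24 matrix genes (median -1.35), where Timp1 had -1.98 and Bgn -2.27 and 1 fell when adjusted over the list alone. Likewise none passed in the antioxidant (Gstp1 1.23, Gpx3 2.01), oxidative phosphorylation (Ndufa2 1.36, Ndufa1 1.51), collecting duct (Hsd11b2 2.49, Scnn1b 1.14), macrophage (Tyrobp 2.55, Csf1r 0.85) and urothelium lists (Upk2 2.54; Krt5 was listed at 0 in the unloaded libraries and had 2.51 ± 1.25 FPKM with 4-PBA, SD, n = 3). When adjusted over the list alone, 1 antioxidant, 2 oxidative phosphorylation, 1 collecting duct, 0 macrophage and 1 urothelium genes rose. These 8 of 28 lists passed camera with a preset correlation, 7 upwards and the matrix list downwards, with camera adjusted p from 3.91e-09 (proximal tubule) to 0.0333 (collecting duct). With an estimated correlation 0 passed, and each had an adjusted p = 0.729 with an estimated correlation. With fry 0 passed too. Camera called 5 lists without HU3, 13 without PBA3 and 14 without a filter on low values, and other splits of these 6 libraries gave up to 10.

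For the stress genes the log2 differences were -0.30 for Hspa5, 0.41 for Ddit3, 0.11 for Atf4, 0.47 for Xbp1, 0.11 for Atf6, 0.10 for Eif2ak3 and -0.30 for Ern1, none past the threshold. Here too 0% of simulated genes changed by a log2 of 1 were found, so changes of that size would mostly go undetected. Of 25 unfolded protein response genes 0 passed, also when adjusted over the list alone; Syvn1 had 1.07 and Derl1 1.31 (camera adjusted p = 0.0911). Of 19 integrated stress response genes the transcription factor Cebpb rose (1.16) and Fgf21 fell, the same when adjusted over the list alone (camera adjusted p = 0.509).

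**Figure D3:**
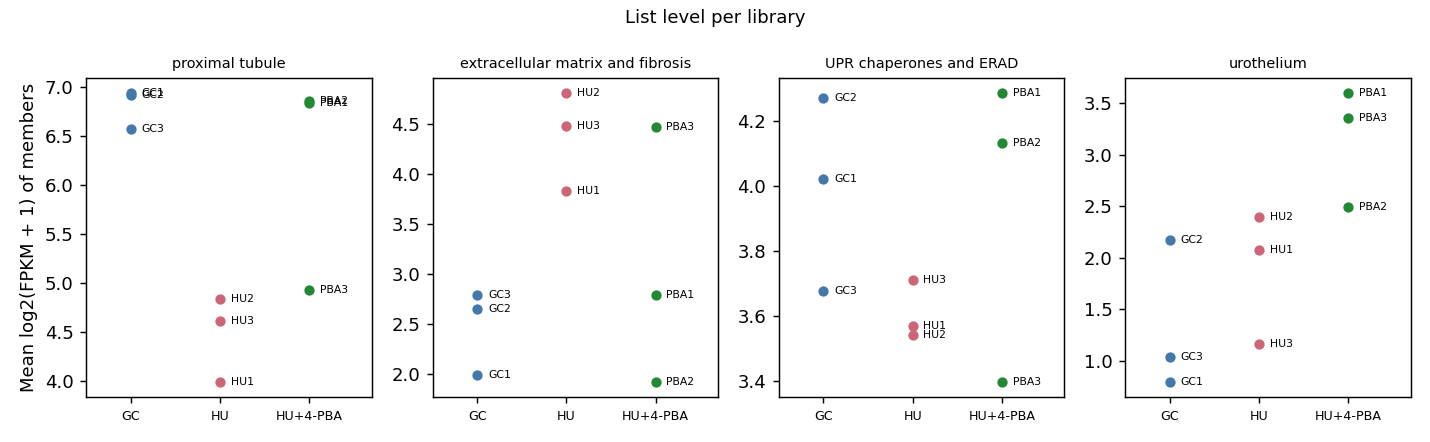
Mean log2(FPKM + 1) of the members of 4 gene lists in each library, with a separate vertical axis for each list. For the proximal tubule list PBA3 (4.93) lay near HU2 (4.83), while PBA1 (6.84) and PBA2 (6.86) lay near the ground controls.

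Leaving out PBA3 raised the count to 1320 in limma, and leaving out PBA1 or PBA2 lowered it to 76 or 36. It was 106, 104 and 131 without GC1, GC2 and GC3 and 216 without HU1, and with only the 6 libraries compared it was 17. Ground controls enter this comparison only through the shared estimate of spread, so the count rested partly on them. With the mitochondrial share as a covariate 91 genes passed, without any filter on low values 17, with the replicate number as a block 137 and with scaling by total reads 689.

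The third question was whether genes changed by unloading were changed back with 4-PBA. Of the 340 genes that differed with 4-PBA, 328 had also passed for unloading with the opposite sign, and 0 with the same sign: 141 were lowered by unloading and 187 raised. The 10 with the largest differences were Slc22a2, Mogat1, Tmem37, Cyp2d9, Slc22a18, Nat8f1, Cyp4a31, Slc34a1, Mettl7b and Slc51a, all lowered by unloading. Slc34a1 had 622 ± 109 FPKM in ground controls, 53.8 ± 40.3 FPKM after unloading and 443 ± 259 FPKM with 4-PBA (SD, n = 3 each). Slc51a, a subunit of a bile acid transporter, had 29.6 ± 8.50, 1.86 ± 1.74 and 29.9 ± 15.6 FPKM (SD, n = 3 each).

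Both comparisons used the same unloaded libraries, which alone gives opposite signs. Across 12642 genes the log2 differences correlated at -0.909, where simulated unchanged groups gave -0.499, and their covariance was -0.718 against a simulated -0.0981. The signs were opposite in 85.8% of genes, against a simulated 66.7%. Simulated groups gave 0.01 genes changed back on average, and independent lists would share 10.3 genes raised then lowered and 7.21 lowered then raised. Neither is a measure for the 328: unchanged groups give a count near 0 by construction, and independent lists ignore the shared libraries. With 1 unloaded library set against ground controls and the other 2 against 4-PBA, or the reverse, no library was shared. The 6 such divisions gave correlations from -0.646 to -0.487, covariances from -0.570 to -0.543 and opposite signs in 66.5% to 71.7% of genes. Simulated unchanged groups divided likewise gave a correlation of -2.20e-05 (SD 0.0149 over 100 simulations) and opposite signs in 49.99% of genes. Genes varied independently of each other in these simulations and not in the libraries, so the simulated SD is too narrow a measure of chance. The count of 328 was not divided in this way, so its excess may come from the shared libraries. Other regroupings that kept the unloaded libraries together and mixed the other 6 gave 326 to 410 genes. The count thus follows the unloaded libraries standing apart, not the division of the rest into ground controls and 4-PBA. With 0 as the ground control mean and 100 as the unloaded mean, the 1292 genes had a median position of 16.7% in PBA1, 0% in PBA2 and 44.8% in PBA3. These genes were called with the 4-PBA libraries in the estimate of spread. That favours genes where PBA3 lay near PBA1 and PBA2, so 44.8% may place PBA3 too near ground controls. The count of 328 became 1273 without PBA3, 73 without PBA1, 35 without PBA2, 62, 95 and 97 without GC1, GC2 and GC3, and 212 without HU1. It was 71 with the mitochondrial share as a covariate, 17 without a filter on low values, 137 with the replicate number as a block and 646 with scaling by total reads. The mitochondrial share was 15.2% in PBA1 and 13.7% in PBA2, the libraries nearer to ground controls, and 67.1% in PBA3.

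The last comparison, 4-PBA-treated unloaded mice against ground controls, asked how far treated unloaded animals differed from untreated ones that were not unloaded. No gene passed in limma (0 of 12642, with 165 at an unadjusted p under 0.05), and limma-voom on recovered reads also called 0. Chance alone would give a share of 0.05, which is more than those 165, so they do not mark a remaining difference. A number under that share does not show that none remains either, as the spread of all 3 groups enters these p-values. Groups did not overlap in 8.00% of genes, where chance gives 10%. The smallest unadjusted p belonged to Mir7052 (log2 difference -2.21), Psca (3.41), Gm26460 (-1.62), Gm49195 (-1.41), Upk3a (3.02), H2-DMb2 (1.13), Nkg7 (1.22), Gsdmc3 (2.00), Gm22753 (2.35) and Gm48194 (-1.32), none past the threshold. Psca and Upk3a are expressed in urothelium, the lining of the renal pelvis. Psca had 48.0 ± 42.9 FPKM with 4-PBA and 3.22 ± 3.61 FPKM in ground controls (SD, n = 3 each). It was 37.6, 11.3 and 95.1 FPKM in PBA1, PBA2 and PBA3 and 1.31, 7.38 and 0.956 FPKM in GC1, GC2 and GC3, and its log2 difference of 3.41 became 2.69 without PBA3 and 4.07 without GC2. In simulated data with the spread of these libraries, 20.8% of genes changed by a log2 of 2 and 0% of those changed by 1 were found in this comparison, so differences of that size would mostly go undetected.

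Camera with a preset correlation called 10 of 28 lists, although 0 of their genes passed. With an estimated correlation 0 lists passed: adjusted p = 0.219 with an estimated correlation for urothelium, 0.306 for intercalated cells, 0.327 for tubular injury and the integrated stress response, 0.399 for macrophages, 0.414 for lymphocytes, 0.651 for matrix, proximal tubule and fatty acid oxidation and 0.692 for oxidative phosphorylation. With fry 0 passed as well. Called upwards were urothelium (median 1.70), matrix (0.62; Col6a2 1.07, Col5a2 -0.45), tubular injury (0.27; Krt18 1.26, Krt19 1.84), lymphocytes (0.95; Trbc2 0.87, Ighm 1.26), macrophages (0.44; H2-Aa 0.67, Cd74 0.66) and the integrated stress response (0.27; Nupr1 1.56, Cebpb 0.41). Downwards were the proximal tubule (-0.59; Slc5a2 -1.09, Miox -0.71), intercalated cells (-0.54; Slc26a4 -0.72, Atp6v0d2 -0.59), oxidative phosphorylation (-0.29; Ndufs7 -0.68, Cyc1 -0.44) and fatty acid oxidation (-0.27; Cyp4a10 -1.36). PBA3 stood apart in several of these lists: the lymphocyte list averaged a log2(FPKM + 1) of 4.05 in PBA3, 1.63 in PBA1 and 1.52 in PBA2, the matrix list 4.47, 2.79 and 1.91, and the proximal tubule list 4.93, 6.84 and 6.86. Ground controls lay between 1.34 and 1.47, 1.99 and 2.79, and 6.58 and 6.94. Nupr1 was 6.93, 7.54 and 43.9 FPKM in PBA1, PBA2 and PBA3. Without PBA3 the log2 difference was 0.74 for Nupr1, 0.23 for Ighm, 0.41 for Trbc2, 0.07 for Col6a2, -0.29 for Slc5a2, -0.21 for Miox, -0.20 for Ndufs7, -0.08 for Cyc1, 0.24 for Cebpb and -0.82 for Cyp4a10. When adjusted over the list alone, 5 of 10 urothelium genes and 0 of the other 9 lists passed. The camera adjusted p ran from 3.60e-12 for urothelium to 0.0455 for the integrated stress response. Camera called 16 lists without GC3 and 6 without PBA3, and other splits of these libraries gave up to 17.

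Stress gene values in this comparison were -0.27 for Hspa5, 0.39 for Ddit3, -0.16 for Atf4, -0.24 for Xbp1, 0.39 for Atf6, 0.37 for Eif2ak3 and 0.27 for Ern1, and Pdia4, a disulfide isomerase of the unfolded protein response list, had 0.39.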

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

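The pseudocounts, the scaling by reads outside the mitochondrial genome, the mitochondrial covariate, the library weights, the omission of both PBA3 and GC3 and the thinning of reads were chosen after seeing the data; the other alternatives were planned. DESeq2 and edgeR were planned for counts and not run on the reads recovered from the FPKM, which were tested with limma-voom; the planned scalings and filters were applied with limma to recovered reads. Over 24 alternatives, the 128 pairs of a named gene and a comparison gave 3054 values: 2530 kept direction and side of the threshold, 445 lost the threshold, 43 gained it and 36 changed sign. None of the 64 pairs past the threshold changed sign (0), but only 8 were still past it with the mitochondrial covariate, 12 without a filter, 17 without GC1, 22 without GC3 and 24 without GC2. Depth limits the low genes: 3 reads were 0.000191% of the reads outside the mitochondrial genome in HU2 and 2.33e-05% in GC2.

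Counts of genes that moved by over 1.5 times are given for unloaded against ground control (1292), 4-PBA against unloaded (340) and changed back (328); the cause was not tested except where fewer genes or samples entered. Scaling by total reads gave 2256, 689 and 646. No filter on low values gave 238, 17 and 17. The mitochondrial covariate gave 109, 91 and 71, and library weights 3983, 2045 and 1951. For the last 2 results, a mean CPM of at least 1 gave 195 and 191, only the compared groups 17 and 17, protein-coding genes alone 200 and 196, a pseudocount of 0.1 145 and 143, and omission of both PBA3 and GC3 1118 and 1044. With the replicate number as a block, 137 and 137 genes passed, and 904 for unloading. The numbers do not pair the samples: same-numbered libraries deviated with correlations from -0.196 to 0.288, and 2 of 9 correlated best with their own number. With 1 sample left out, counts ranged from 69 to 2360, 36 to 1320 and 35 to 1273. For 4-PBA against ground control, limma gave 0 genes under every alternative run for it, limma-voom and each omission included (165 at an unadjusted p under 0.05 in the reported test).

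Gene lists numbered 6, 8 and 10 in the 3 comparisons. Without a filter there were 15 for unloading and 14 for 4-PBA against unloaded, with the mitochondrial covariate 2 for unloading, and without both PBA3 and GC3 5 for 4-PBA against unloaded. With an estimated correlation 0, 0 and 0 passed, and with fry 1, 0 and 0; the cause was not tested. With 1 sample left out the lists ranged from 5 to 8, 5 to 13 and 6 to 16.

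The 36 values that changed sign all belong to endoplasmic reticulum stress genes not past the threshold, and the cause was not tested. For unloaded against ground control, Hspa5 was -0.000525 with median-of-ratios scaling, -1.02 with total reads, -0.02 without HU2, -0.04 without HU3, between -0.18 (without GC3) and 0.22 (without GC2) with 1 sample left out, and -0.18 without both PBA3 and GC3. Ddit3 was 0.024 with limma-voom, 0.07 without GC1, 0.05 without GC3, between -0.17 (without GC2) and 0.19 (without HU1) with 1 sample left out, 0.19 with scaling by reads outside the mitochondrial genome, 0.043 with library weights and 0.049 without both PBA3 and GC3. With total reads Atf6 was -0.45 and Eif2ak3 -0.41, and with the mitochondrial covariate Xbp1 was 0.00268. For 4-PBA against unloaded, Hspa5 was 0.67 with total reads, between -0.48 (without PBA1) and 0.00884 (without PBA3) with 1 sample left out and 0.00884 without both PBA3 and GC3. Ern1 was 0.27 with total reads, 0.077 with library weights, and between -0.62 (without HU3) and 0.081 (without HU1) with 1 sample left out. Atf4 was between -0.044 (without HU2) and 0.20 (without PBA3) with 1 sample left out and -0.025 with scaling by reads outside the mitochondrial genome. Eif2ak3 was between -0.063 (without HU3) and 0.30 (without HU1) with 1 sample left out, -0.013 without PBA1 and -0.013 after thinning. With the mitochondrial covariate Xbp1 was -0.20 and Atf6 -0.20, and with library weights Ddit3 was -0.27. For 4-PBA against ground control, with 1 sample left out Hspa5 was between -0.48 (without GC3) and 0.038 (without PBA3) and Xbp1 between -0.43 (without PBA2) and 0.10 (without PBA3), with library weights Ddit3 was -0.22 and Xbp1 0.0010, and without both PBA3 and GC3 Atf4 was 0.021 and Xbp1 0.011.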

Other observations

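The tests of the mitochondrial share, of thinned reads, of the rate of calls among chemoreceptor genes and of the urothelial markers (both correlations) were chosen after the results were seen; the other splits of the samples and the comparison of rises with chemoreceptor genes were set down before theirs. The lists not described so far had few genes past the threshold for unloaded mice against ground controls. Of 14 tubular injury genes 2 rose and 1 fell, while 3 and 2 did when adjusted over the list alone. In fatty acid oxidation 1 of 24 genes rose and 3 fell (2 and 5 adjusted over the list alone), and in cholesterol synthesis 1 of 18 rose and 2 fell (1 and 3). Among collecting duct genes 2 of 9 fell (3 adjusted over the list alone), among renin angiotensin genes 1 of 8 (3), among podocyte genes 1 of 9 (4) and among distal convoluted tubule genes 1 of 8 (1). Rises were seen in 2 of 11 endothelial genes, 1 of 17 apoptosis genes, 1 of 18 interferon genes, 1 of 13 glucocorticoid genes, 1 of 8 liver genes and 1 of 6 lymphocyte genes, with the same numbers when adjusted over the list alone except for liver, where 2 rose and 2 fell. No gene passed over all genes among 7 erythroid genes (4 fell when adjusted over the list alone), nor by either count among 9 inflammation, 15 circadian, 8 loop of Henle, 13 macrophage, 11 adipocyte and 10 urothelium genes. None of these lists passed camera in this comparison, and 6 lists (proliferation, neutrophil, adrenal cortex, adrenal medulla, pancreas and skeletal muscle) had fewer than 4 tested members and 0 genes past the threshold. With 4-PBA against unloaded mice, 1 gene rose in each of the fatty acid oxidation, renin angiotensin, distal convoluted tubule and lymphocyte lists, and 1 fell in each of the fatty acid oxidation and liver lists. Adjusted over the list alone, 4 rose and 2 fell in fatty acid oxidation, 2 rose and 1 fell among lymphocyte genes, 2 fell among liver genes and 1 rose in each of the other 2 lists; 3 rose and 1 fell in tubular injury, 3 rose among erythroid genes and 1 fell in cholesterol synthesis. Adipocyte genes averaged a log2(FPKM + 1) of 4.83 in GC2 and 4.96 in PBA3, and 1.52 to 2.20 in the other 7 libraries.

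The genes changed by unloading came from libraries with a mitochondrial share of 63.7% to 79.3%, so a lower yield or quality of RNA may have contributed, and an effect of unloading stays open beside it. With the mitochondrial share in the model, the median difference of the called genes kept 83.7% of its size (1.70 to 1.43) while the median SE went from 0.36 to 0.45 and 76 of 1292 stayed past the threshold; this value was set aside, as genes called for their small spread favour a high figure. Over all 12642 genes the slope of the differences with the covariate on those without it was 0.720, between the bounds of 0.25 and 0.75 set for either answer, so the share and unloading cannot be told apart, the share being tied to the groups. Depth alone was excluded as the whole cause: with reads thinned to the shallowest library, 80.0% of the genes called were called again, although thinning does not copy a loss of library complexity. GC3, with a share of 49.7%, had a proximal tubule mean of 6.58, near GC1 and GC2, and PBA3, with 67.1%, had 4.93. The same may hold for the genes changed back by 4-PBA, as PBA1 and PBA2 had low shares: with the share in the model 71 genes were called in place of 328, so RNA quality stays open there beside an effect of the drug.

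Genes raised by unloading could reflect uniform background reads, as chemoreceptor genes, taken as silent in kidney, held 0.0509% to 0.175% of reads outside the mitochondrial genome in the unloaded libraries, 0.0505% in PBA3 and 0.0032% to 0.0068% in ground controls. All rises of called genes, 100% of protein-coding and 100% of other genes, exceeded the 99th percentile of chemoreceptor rises (1.14 FPKM), but the minimum of 1 FPKM in 3 libraries all but fixes that outcome, so it decides nothing. Of 1350 chemoreceptor genes 1 was called as raised. Over the 377 of 455 raised protein-coding genes within their range of lengths, that rate gives 3.21% of the calls. Its upper 95% limit gives 17.9%, under the bound of 25% set for excluding uniform background as the main source of those 377. That rate counts chemoreceptor genes too low for the filter of 1 FPKM in 3 libraries, which could not be called. Genes with expression of their own pass the filter more easily, so the rate may be too low for them. Uniform background is thus not excluded for the 377. With the 78 genes outside that range counted as background the limit is 31.9% of all 455, over the bound of 25% set for excluding it. For other genes the rate gives 9.58% of the 84 calls within the range, with an upper limit of 53.3%, and with the 133 outside it counted as background the limit is 81.9% of 217. For those genes and for the protein-coding genes, background and an effect of unloading cannot be told apart. Chemoreceptor reads were not spread evenly: HU1, HU2 and HU3 had 2878, 2740 and 1546 reads on 106, 343 and 186 of 1796 such genes of any length and class. Background piled up on few genes, which the test of a uniform rate cannot exclude, stays open.

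Urothelial markers in the 4-PBA samples may follow a different share of renal pelvis in the tissue taken. The 10 tested members correlated with each other over the 9 libraries at a mean of 0.456, at the 99.99 percentile of 9971 random lists matched on expression; this value was set aside, as the list was noticed for its level with 4-PBA and a joint response would give the same. In the 6 libraries without 4-PBA, with group means removed, the correlation was 0.354, at the 99.4 percentile of 9972 random lists, so the members also varied together where no drug was given. The list averaged a log2(FPKM + 1) of 3.60, 2.49 and 3.36 in PBA1, PBA2 and PBA3, 2.17 in GC2 against 0.79 and 1.04 in GC1 and GC3, and 2.08, 2.40 and 1.16 in HU1, HU2 and HU3, so HU2 lay near PBA2. Why the 4-PBA samples would hold more urothelium is not answered by these values. A response of urothelium to 4-PBA was not tested and stays open.

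The 6 libraries of each pair of groups can be split in 10 ways, too few for a share under 0.05. For unloaded against ground control 1 split, the real one, gave as many genes (1292, highest other 0), and 7 splits gave as many lists (6, highest other 12). For 4-PBA against unloaded, 1 split gave as many genes (340, highest other 163, with PBA3 beside HU2 and HU3) and 5 as many lists (8, highest other 10). For 4-PBA against ground control 10 splits gave as many genes (limma 0, highest other 1, 165 at an unadjusted p under 0.05 in the real split) and 8 as many lists (10, highest other 17). Of 100 regroupings of all 9 libraries, 4 gave as many genes changed back (328, highest other 410), the real one included. Each of the 4 kept the 3 unloaded libraries together, as did another that gave 326, so the share under 5% rests on 326 against 328 and is not taken to exclude chance for the genes changed back. With the unloaded libraries parted the highest was 165, so the count follows these libraries standing apart from the other 6 and not the division of those 6 into ground controls and 4-PBA.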
